A study of Mus musculus with 10 samples.

How the data were processed

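RNA from mouse cortical neurons in culture was sequenced as 10 polyA libraries in 4 groups: control virus, control virus with BDNF, H2BE virus, and H2BE virus with BDNF. Per the labels AraC was used at 0.5 µM and RNA was taken 24 h after BDNF. The authors' notes name the mouse genome build mm10, SAMtools, DESeq2 and deepTools without versions. The aligner, the counting tool and the annotation release are not given in the sources used here. The first table the authors deposited holds raw counts for 48526 Ensembl genes in each library. The second deposited table holds signal values, normalized counts, in which the raw counts of each library are divided by 1 size factor. It lists 21862 genes, exactly those with at least 1 count in at least 3 libraries, and 4159 of them without a symbol. The raw counts were used for every test, and the normalized table only for gene symbols. All 10 libraries have a column in both tables.

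Before any comparison the libraries of each group were compared gene by gene. Control replicate 3 exceeded Control replicate 1 at 0 genes, and BDNF replicate 3 exceeded BDNF replicate 1 at 0 genes. The correlation of log2 CPM was 0.9988 in the former and 0.9976 in the latter, and the spread of counts (chi-squared per degree of freedom 0.639 and 0.847) was below that of independent counting. Every other pairing within a group had a correlation of 0.9886 to 0.9917 and a spread of 1.67 to 5.16. The third replicates thus hold a subset of the counts of the first. The larger library of each such pair was used in the tests, which left 8 distinct libraries, 2 per group. For means and SD the CPM of both were averaged as 1 sample. The grouping set before the data were examined counted all 10 libraries as replicates, and after this finding that fit became an alternative.

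Of 48526 genes 21822 had no counts. The edgeR function filterByExpr with a minimum count of 10 and a minimum total of 15 kept 13452 genes, which hold 99.78% of counts. Libraries were scaled by TMM, and a quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) was run with a mean per group. The comparisons were BDNF against Control, H2BE against Control, H2BE+BDNF against H2BE, H2BE+BDNF against BDNF, and the difference between the BDNF responses under both viruses. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 within each comparison. Adjusted p-values for genes are from edgeR unless DESeq2 is named. Log2 CPM used a prior count of 2.

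The depth sets the precision. A floor of 3 counts is 0.21 CPM in the deepest library and 0.593 CPM in the shallowest. In counts simulated with the fitted dispersion, the test recovered 56.9% of changes of 0.5 on the log2 scale, 83.1% of 1 and 95.5% of 2 for BDNF against Control. For H2BE against Control it recovered 48.5%, 81.8% and 96.9%, and for the difference of responses 33.3%, 58.2% and 89.2%. False calls were 4.38% to 9.94% of calls. A simulated length trend of 0.15 log2 per doubling between H2BE and Control gave 559 calls, and 1 after the length and GC correction. That trend was steeper than the gap between the observed mean slopes, -0.0481 in Control and 0.0208 in H2BE. The 559 calls are therefore no estimate of what the observed trend would give. A gene with 1 to 3 counts in a group was given as a ratio with a 95% counting interval.

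The genes named in each comparison are up to 10 of the largest log2 fold changes in each direction among called genes with a mean of at least 5 CPM (5 per direction for the difference of responses), and H2bc21. They also needed a symbol that is not provisional and, except for the difference of responses, CPM that did not overlap between the groups compared. Rankings such as the largest rise refer to genes that met these rules. In addition 26 gene lists, written from general knowledge before the data were examined, were tested with camera (limma) at a preset correlation of 0.01, with p adjusted over all 130 list tests. They cover immediate-early genes, secreted factors, ERK feedback, Trk receptors, ATF4 and unfolded protein response, cholesterol, postsynaptic, presynaptic, GABA, ion channel, axon and cytoskeleton, ribosomal, nuclear and mitochondrial respiratory, core and replacement histone, chromatin, interferon, p53 and marker genes of excitatory neurons, interneurons, astrocytes, oligodendrocytes, microglia, endothelial, mural and fibroblast cells, and progenitors. The named members of a list are up to 4 with the smallest p in that comparison. A few of these members are followed into the other comparisons. The test was repeated with a correlation estimated from each list. A list absent from a comparison's text was not called there.

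Genes were named by the normalized table (12822), or by the reference for mouse genes (587), and 43 kept their Ensembl ID. Coordinates and transcript lengths are from GENCODE M21, which holds 48144 of the gene IDs, and 99.68% of tested genes had a length. The length and GC correction fitted a lowess curve (span 0.3) of each library's log2 CPM, relative to the mean, on transcript length and then on GC content, and used it as an offset. Correlations between comparisons were computed over all 13452 genes, and the part due to shared libraries was simulated without effects.

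Alternatives set before the data were examined were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a block for replicate number, only replicates 2 and 3, only the groups compared, and leaving out each library in turn, where leaving out replicate 1 of Control or BDNF also leaves out replicate 3. A group then left with 1 library takes its spread from the other groups. Added afterwards were the length and GC correction, a rounded mean of the overlapping libraries, a crossed block, thinning to the smallest library and, for the correlation of BDNF and H2BE changes, a Control library for each comparison. Reads were not aligned again here, and splicing, repeats and allele-specific expression were not analysed here.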

Results

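Gene expression was measured by polyA RNA sequencing in primary neurons from the cortex of wild-type mouse embryos. The cultures had been given AraC, which kills dividing cells. They then received a lentivirus carrying H2BE, a variant of histone H2B, or a control lentivirus. BDNF, a secreted neurotrophin that acts through the receptor TrkB, was added to part of the cultures and RNA was taken 24 h later. The 10 libraries make 4 groups: control virus (Control, 3 libraries), control virus with BDNF (BDNF, 3), H2BE virus (H2BE, 2) and H2BE virus with BDNF (H2BE+BDNF, 2). Total counts were 14142545, 5682480 and 10419437 in Control replicates 1 to 3, and 11730663, 12472505 and 7256573 in BDNF replicates 1 to 3. They were 7076365 and 5058074 in H2BE replicates 2 and 3, and 8357276 and 6970221 in H2BE+BDNF replicates 2 and 3.

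The third replicates of Control and BDNF are not separate samples in these counts. At 0 of 48526 genes did Control replicate 3 hold more counts than Control replicate 1, and its total was 73.7% of that of replicate 1. The same held for BDNF replicate 3, at 61.9% of the total of BDNF replicate 1. Each was therefore counted together with replicate 1 as a single sample, which leaves n = 2 distinct libraries in every group. Levels below are CPM, counts scaled to the TMM-adjusted total of the library, as mean ± SD over those samples. The p-values measure only the spread between these samples, because the labels do not say whether replicates were separate cultures. On the leading principal component, with 53.8% of the variance, the libraries without BDNF lay between -29.13 and -24.33 and those with BDNF between 25.11 and 30.06.

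The histone gene carried by the virus, H2bc21 (ENSMUSG00000068854, chromosome 3, 96221119 to 96223738, plus strand), encodes H2BE. Its RNA was 5.27 ± 0.074 CPM in Control and 39.1 ± 5 CPM in H2BE, a rise of 7.58-fold (log2 fold change 2.92, SE 0.16, adjusted p = 1.45e-08, n = 2). With BDNF it was 3.98 ± 0.15 CPM under the control virus and 33.6 ± 2.2 CPM under the H2BE virus, 8.61-fold higher (log2 fold change 3.11, SE 0.16, adjusted p = 5.17e-09). This placed H2bc21 at rank 5529 of 13452 genes by level in H2BE and at rank 10582 in Control. BDNF itself left it uncalled, at a log2 fold change of -0.42 (adjusted p = 0.132) with the control virus and -0.24 (adjusted p = 0.172) with the H2BE virus. The counts do not separate RNA made from the virus from RNA of the neurons' own gene, and reads of near-identical H2B genes can be shared among them. None of the 6 other core histone genes tested changed with the H2BE virus (list adjusted p = 0.397). Among 11 replacement histones 1 fell, H2az2, which encodes an H2A variant placed at promoters, from 8.28 ± 1.1 to 3.37 ± 0.01 CPM (log2 fold change -1.26, adjusted p = 0.0202), a call lost without Control replicate 1 (adjusted p = 0.193), Control replicate 2 (0.0691), H2BE replicate 2 (0.233) or H2BE replicate 3 (0.0805) and after correction for transcript length and GC content (0.0915), at log2 fold changes between -1.42 and -1.14.

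**Figure D1:**
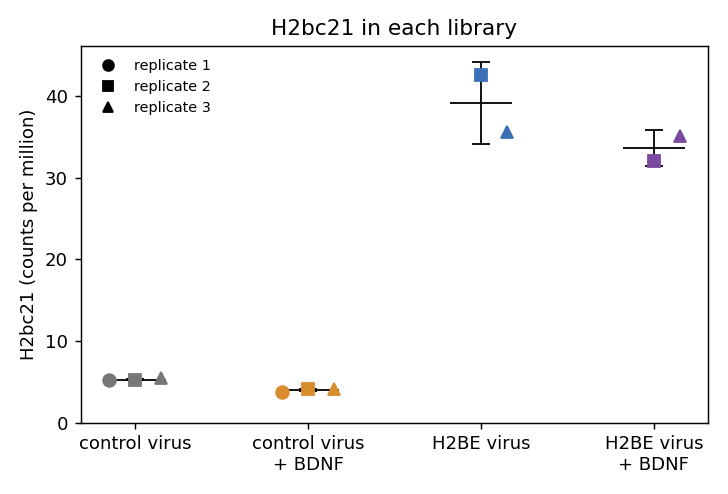
H2bc21 RNA in CPM (vertical axis) in each library of the 4 groups, with the mean and SD over the distinct samples. The level is 5.27 in Control, 3.98 in BDNF, 39.1 in H2BE and 33.6 in H2BE+BDNF.

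BDNF changed a broad set of genes in neurons with the control virus. Arc, an immediate-early gene whose protein removes glutamate receptors from synapses, rose from 2.87 ± 0.61 to 39.8 ± 8 CPM (log2 fold change 3.97, adjusted p = 9.47e-10, n = 2). Galr1, the receptor for the neuropeptide galanin (chromosome 18, 82392380 to 82406777, minus strand), rose from 0.343 ± 0.25 to 11.9 ± 0.12 CPM. Pcsk2, a protease that cuts prohormones into active peptides (chromosome 2, 143546156 to 143816285, plus strand), fell from 132 ± 1.7 to 34.5 ± 3.9 CPM (log2 fold change -1.90, adjusted p = 1.6e-11). Grm2, an inhibitory glutamate receptor of axon terminals, fell from 48.4 ± 1.7 to 12.7 ± 5.2 CPM. In all, 4228 of 13452 genes (31.4%) were called, 2257 up and 1971 down, and 678 of them changed more than 2-fold. DESeq2 called 2602.

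Transcription factors of the early growth response family were among the largest rises, Egr1 from 9.58 ± 3.4 to 109 ± 18 CPM and Egr2 from 1.56 ± 1.2 to 10.1 ± 0.92 CPM. So were 2 immune-type genes, the interferon-inducible Ifi209 (log2 fold change 5.10) and the small GTPase Gimap6 (4.62, from 0.667 ± 0.7 to 21.9 ± 3.1 CPM). The aldose reductase relative Akr1b8 (3.71), the peptide transmitter gene Grp (3.27), the noncoding RNA Mirt1 (3.14) and the Ras-like gene Rasl11a (2.92) complete the 10 largest rises. The largest falls were Trip10, a membrane-bending adaptor (12.3 ± 2.1 to 1.98 ± 0.56 CPM, log2 fold change -2.68), and Pacsin3, also a membrane-bending protein (27.8 ± 2.9 to 5.14 ± 0.91 CPM, -2.42). They were followed by Ypel1 (-2.13), the lipid transporter Abca8a (-2.07), the sodium-calcium exchanger Slc24a4 (-2.04), the natriuretic peptide receptor Npr3 (-1.83, adjusted p = 0.00499), the signalling adaptor Sla (-1.68) and the peptidase Ace (-1.68). Npr3 lost its call without Control replicate 1 (adjusted p = 0.0996) or Control replicate 2 (adjusted p = 0.0506).

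Signalling genes moved as groups. Of 17 feedback genes of the ERK pathway, which BDNF activates through TrkB, 15 rose, and 15 rose when p was adjusted over the list alone (median log2 fold change 1.2, adjusted p = 1.22e-25; adjusted p = 0.134 with an estimated correlation). Spred3 went from 71.1 ± 2.2 to 183 ± 4.5 CPM, and Spry4 (log2 fold change 1.75), Etv5 (1.32) and Spry2 (1.20) rose with it. Of 20 immediate-early genes 15 rose, 16 over the list alone (median 0.796, adjusted p = 2.3e-13; adjusted p = 0.134 with an estimated correlation), among them Fosb (5.36 ± 0.93 to 27.2 ± 4.6 CPM), Fos (log2 fold change 1.04) and Jun (0.70). Of 21 secreted factors and neuropeptides 13 rose and 2 fell, 15 and 2 over the list alone (adjusted p = 7.55e-13; adjusted p = 0.184 with an estimated correlation). Vgf, a precursor of neuropeptides, rose from 703 ± 19 to 1580 ± 4 CPM, Nptx1, which clusters glutamate receptors, from 34.4 ± 3.9 to 182 ± 24 CPM, and Scg2, a granule protein, from 615 ± 31 to 1370 ± 180 CPM. Of 28 genes of the ATF4 and unfolded protein response 23 rose, 26 over the list alone (median 0.476, adjusted p = 2.62e-13; adjusted p = 0.151 with an estimated correlation), led by the serine synthesis gene Psat1 (92.1 ± 4.7 to 172 ± 17 CPM) and the chaperone Hspa5 (log2 fold change 0.49).

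Cholesterol and postsynaptic genes rose more modestly. Of 25 cholesterol genes 12 rose and 2 fell, with the same counts over the list alone (adjusted p = 0.00116; adjusted p = 0.628 with an estimated correlation), including the synthesis genes Sc5d (log2 fold change 0.58) and Stard4 (0.56). Without BDNF replicate 1 that list was no longer called (adjusted p = 0.203). Of 35 postsynaptic genes 16 rose and 4 fell, 16 and 5 over the list alone (adjusted p = 0.00355; adjusted p = 0.318 with an estimated correlation), among them the scaffolds Homer1 (109 to 182 CPM) and Dlg4 (464 to 729 CPM). A correction for transcript length and GC content ended that list call (adjusted p = 0.0727). Among presynaptic genes 8 rose and 10 fell of 34 (9 and 10 over the list alone, adjusted p = 0.461; the test pointed up and the median was -0.0402), with rises of Slc17a6 (48 to 108 CPM), which loads glutamate into vesicles, and of the active zone proteins Pclo and Bsn (log2 fold changes 0.74 and 0.70).

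Markers of other cells moved in the same cultures. Vim, an intermediate filament of progenitors and glia, rose from 63.4 ± 5.1 to 174 ± 7 CPM, Cd68 of microglia from 4.85 ± 0.47 to 17.7 ± 0.95 CPM and Mbp of oligodendrocytes from 19.8 ± 0.0058 to 51.8 ± 1 CPM. Of 10 oligodendrocyte genes 3 rose, also over the list alone (adjusted p = 0.0432; adjusted p = 0.25 with an estimated correlation). That call was lost without Control replicate 1 (adjusted p = 0.0509), BDNF replicate 1 (0.0541) or BDNF replicate 2 (0.123). Replacement histones fell, 6 of 11 both over all genes and over the list alone (adjusted p = 0.00792; adjusted p = 0.302 with an estimated correlation), with H2az1 and H2az2 at log2 fold changes of -0.53 and -1.39.

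The count of BDNF genes was 2316 without Control replicate 1, against 4228 with all distinct libraries. It was 6460 with all 10 libraries as replicates.

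With the H2BE virus, BDNF acted on much the same genes. Arc rose from 1.89 ± 0.71 to 37.6 ± 2.6 CPM (log2 fold change 4.24, n = 2), Vgf from 628 ± 4.9 to 1440 ± 27 CPM and Nptx1 from 39.2 ± 1.1 to 185 ± 3.1 CPM. Pcsk2 fell from 144 ± 1.4 to 31.4 ± 2.2 CPM (log2 fold change -2.21, adjusted p = 1.32e-11) and Grm2 from 55.9 ± 2.3 to 12 ± 0.57 CPM. Vcan, a matrix proteoglycan, fell from 122 ± 14 to 30.8 ± 3.8 CPM. In all, 3484 genes (25.9%) were called, 1822 up and 1662 down, 557 of them over 2-fold. DESeq2 called 2311.

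Ifi209 had 1 count in the H2BE libraries and 233 in those of H2BE+BDNF, a ratio of 184 (95% counting interval 32.8 to 7310). After it the largest rises were Galr1 (log2 fold change 5.09), Gimap6 (5.01), Arc, Mirt1 (3.52), Akr1b8 (3.51), Egr2 (3.15), Rasl11a (2.88), Egr1 (2.79) and Radx (2.78), a regulator of replication forks. Other large falls, besides Grm2, Pcsk2 and Vcan, were Pacsin3 (-2.20), Slc24a4 (-2.15), Ypel1 (-2.08), Trip10 (-1.81), the neurotensin receptor Ntsr1 (-1.78) and the transcription cofactor Lmo1 (-1.72). Across all 13452 genes the BDNF log2 fold changes under both viruses had a Pearson correlation of 0.714 and a rank correlation of 0.595. Of the genes called under both viruses 1165 rose in both and 1035 fell in both (306 and 244 if independent), and 30 moved in opposite directions.

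**Figure D2:**
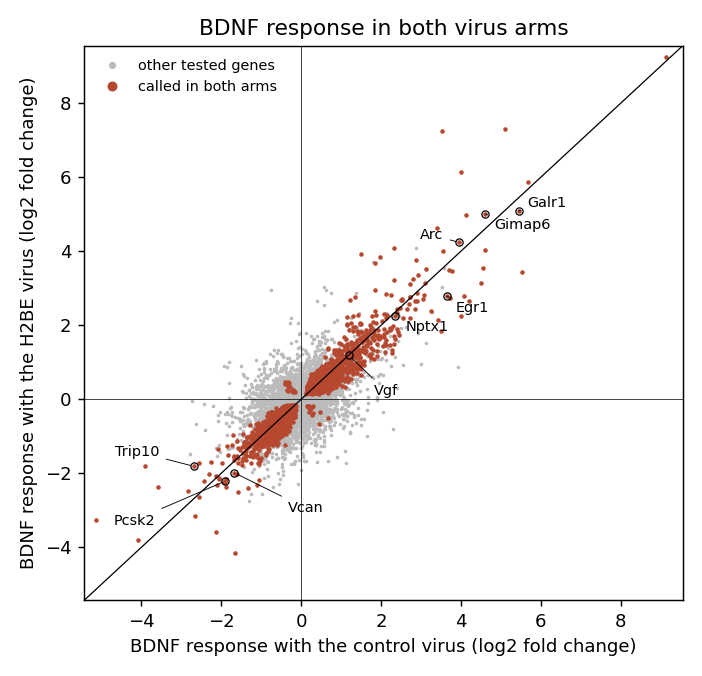
Log2 fold change with BDNF under the control virus (horizontal axis) and under the H2BE virus (vertical axis) for all 13452 genes, with genes called under both in red and the line of equal change. The Pearson correlation is 0.714; the farthest points include genes with few counts.

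The signalling groups rose again under the H2BE virus. ERK feedback genes rose at 11 of 17, 14 over the list alone (median 1.08, adjusted p = 5.32e-23; adjusted p = 0.134 with an estimated correlation), led by Spred3 (log2 fold change 1.27), Spry2 (1.22) and Etv5 (1.18). Immediate-early genes rose at 13 of 20, also 13 over the list alone (median 0.62, adjusted p = 2.24e-10; adjusted p = 0.134 with an estimated correlation), with Fosb from 6.06 ± 0.18 to 20.1 ± 3 CPM and Fos at 0.76. Secreted factors rose at 13 and fell at 2 of 21, the same over the list alone (adjusted p = 1.05e-15; adjusted p = 0.19 with an estimated correlation), and the granule protein Chgb fell (log2 fold change -0.74). ATF4 and unfolded protein genes rose at 21 of 28, 22 over the list alone (median 0.437, adjusted p = 2.3e-13; adjusted p = 0.181 with an estimated correlation), including Hspa5 (0.67) and Hsp90b1 (0.56). Cholesterol genes rose at 7 and fell at 1 of 25, 9 and 1 over the list alone (adjusted p = 0.0125; adjusted p = 0.692 with an estimated correlation), a call lost without H2BE+BDNF replicate 3 (adjusted p = 0.0573).

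Ribosomal protein genes rose with BDNF as a list under the H2BE virus. There 58 of 69 rose, 60 over the list alone (adjusted p = 5.58e-15; adjusted p = 0.301 with an estimated correlation), with Rpl7a from 212 ± 4.1 to 288 ± 6.9 CPM and Rpl12 from 137 ± 5.4 to 205 ± 14 CPM. With the control virus 7 rose and 4 fell, 1 and 1 over the list alone (adjusted p = 0.61), but after the length and GC correction 31 rose and 2 fell and the list was called up there too (median 0.164, adjusted p = 0.00187). Respiratory chain genes of the nucleus rose at 24 and fell at 1 of 59 under the H2BE virus, 26 and 1 over the list alone (adjusted p = 0.000524; adjusted p = 0.428 with an estimated correlation), with Ndufa5 at 0.62. Under the control virus 2 rose and 14 fell, 2 and 12 over the list alone (adjusted p = 0.0331; adjusted p = 0.639 with an estimated correlation). That fall was lost without Control replicate 1 (adjusted p = 0.294) or BDNF replicate 1 (0.0716), and after the length and GC correction the list median turned to 0.018.

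Genes of inhibition and excitability fell with BDNF under the H2BE virus. Of 22 GABA genes 3 rose and 8 fell, 3 and 9 over the list alone (adjusted p = 0.000902; adjusted p = 0.439 with an estimated correlation), with the GABA transporter Slc6a11 at -1.40 and the receptor subunit Gabra5 at -0.55. Under the control virus 3 rose and 9 fell, 4 and 9 over the list alone, and the list was not called (adjusted p = 0.193). Of 35 ion channel genes 2 rose and 14 fell, 4 and 16 over the list alone (adjusted p = 0.00257; adjusted p = 0.301 with an estimated correlation), with the calcium channel Cacna1g at -0.99 and the potassium channel Kcnq5 at -0.62. In the control-virus cultures 9 channel genes rose and 10 fell, 11 and 10 over the list alone (adjusted p = 0.39), where the test pointed up and the median was -0.021. Presynaptic genes rose at 3 and fell at 14 of 34, 3 and 16 over the list alone (adjusted p = 0.0217; adjusted p = 0.19 with an estimated correlation), while 8 postsynaptic genes rose and 9 fell of 35, 10 and 10 over the list alone (adjusted p = 0.785, median -0.057 and mean 0.00792). The presynaptic call was lost without H2BE+BDNF replicate 3 (adjusted p = 0.0693, median -0.127) and after the length and GC correction (adjusted p = 0.0895, median -0.115), with the median close to the -0.135 of all distinct libraries.

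In the same libraries Vim rose from 57 ± 3.1 to 182 ± 8.3 CPM and Cd68 from 3.51 ± 0.21 to 18.5 ± 0.96 CPM. The 16 progenitor genes, with 2 rising over all genes and over the list alone, were called up (adjusted p = 0.0306; adjusted p = 0.226 with an estimated correlation), a call lost without H2BE+BDNF replicate 3 (adjusted p = 0.0636) or after length and GC correction (0.0522). Under the control virus 6 of them rose and 2 fell, 7 and 2 over the list alone (adjusted p = 0.0703). Of 10 oligodendrocyte genes 2 rose, Mbp (1.26) and Lhfpl3 (0.81), and 2 over the list alone (adjusted p = 0.0264; adjusted p = 0.25 with an estimated correlation), a call lost without BDNF replicate 1 (adjusted p = 0.0549) or H2BE replicate 3 (0.0504). The 3484 BDNF genes under the H2BE virus became 1923 without H2BE replicate 2 and 2286 without H2BE+BDNF replicate 2.

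H2BE without BDNF changed fewer genes, by smaller amounts. After H2bc21 itself the largest rise among genes that met the naming rules was Tacr3, a receptor for neurokinin peptides. It went from 2.62 ± 0.23 to 5.06 ± 1 CPM (log2 fold change 1.04, adjusted p = 0.0465, n = 2). Its call was lost after the length and GC correction (adjusted p = 0.114), after thinning to the smallest library (0.151), with replicates 2 and 3 alone (0.0864), and without Control replicate 1 (0.473), Control replicate 2 (0.0721), H2BE replicate 2 (0.455), H2BE replicate 3 (0.0634), H2BE+BDNF replicate 2 (0.0587) or H2BE+BDNF replicate 3 (0.0582), at log2 fold changes between 0.80 and 1.20. Hivep3, a zinc finger transcription factor, rose from 26.3 ± 2.7 to 47.3 ± 2.1 CPM (0.87, adjusted p = 0.000603), and ND4, a respiratory chain gene of the mitochondrial genome (chromosome M, 10167 to 11544), from 1440 ± 140 to 2240 ± 81 CPM (0.57, adjusted p = 1.18e-05). Ndufb7, a respiratory chain gene of the nucleus, fell from 67.9 ± 2.5 to 46.9 ± 0.9 CPM (-0.50, adjusted p = 0.00661). In all, 340 genes were called, 207 up and 133 down, and 4 of them changed more than 2-fold. DESeq2 called 301, and 2454 genes had an unadjusted p below 0.05 in edgeR.

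Other rises were Dyrk1b, a kinase of cell cycle exit (log2 fold change 0.87), Nhsl2 (0.81), the Mediator subunit Med12 (0.63), Prr36 (0.63), the chromatin reader Atad2b (0.60) and the semaphorin Sema4d (0.56). Other falls were Alkbh7 (-0.72), the kinase Yes1 (-0.65), the acetyltransferase subunit Naa38 (-0.59), the mitochondrial ribosome gene Mrps12 (-0.54), the signalosome subunit Cops9 (-0.52), Slc7a6os (-0.51), Nudt9 (-0.49), Ndufb3 (-0.48) and Ccdc71l (-0.48). Without Control replicate 1 only H2bc21 and ND4 were called. Without H2BE replicate 2 the calls were 11 rises and no fall, and of the named genes H2bc21, Hivep3 and ND4 stayed called, while Med12 went to 0.37 (adjusted p = 0.447). After the length and GC correction (adjusted p up to 0.212) and without H2BE replicate 3 the calls of Dyrk1b, Nhsl2, Atad2b, Sema4d, Alkbh7, Yes1, Naa38, Mrps12, Slc7a6os, Nudt9, Ndufb3 and Ccdc71l were lost, and the correction also ended that of Med12 (adjusted p = 0.123). After the correction Dyrk1b was at 0.88, Nhsl2 at 0.61, Sema4d at 0.525, Atad2b at 0.52 and Med12 at 0.52. Yes1 was at -0.62, Alkbh7 at -0.59, Ccdc71l at -0.48, Slc7a6os at -0.47, Naa38 at -0.435, Mrps12 at -0.42, Nudt9 at -0.41 and Ndufb3 at -0.30. Without Control replicate 2 the calls of Med12, Alkbh7, Yes1, Naa38, Mrps12, Slc7a6os, Nudt9 and Ccdc71l were lost (adjusted p between 0.0514 and 0.14), and without H2BE+BDNF replicate 2 or 3 those of Yes1, Naa38 and Ccdc71l (adjusted p between 0.0511 and 0.0587).

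Genes of protein synthesis and respiration in the nucleus fell together. Respiratory chain genes fell at 20 of 59, 47 over the list alone (adjusted p = 4.45e-32; adjusted p = 0.184 with an estimated correlation), among them Atp5mc3 (340 ± 17 to 264 CPM), Ndufb8 (-0.42) and Cox6b1 (-0.36). Ribosomal protein genes fell at 16 of 69, 51 down and 1 up over the list alone (adjusted p = 8.24e-26; adjusted p = 0.226 with an estimated correlation), with Rps14 from 179 ± 3.3 to 132 ± 1.8 CPM. Both lists are of short transcripts, and the length and GC correction kept their calls but moved the medians from -0.228 to -0.134 and from -0.215 to -0.106, with 2 respiratory falls and no ribosomal fall left. The listed genes of the mitochondrial genome went the other way. Of 8 tested 4 rose, 6 over the list alone (adjusted p = 1.79e-09, and 0.19 with an estimated correlation), with ND2 at 0.34 and ND5 at 0.36. Together the listed mitochondrial genes held 2.7 ± 0.078% of all counts in Control and 3.16 ± 0.14% in H2BE.

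A minority of synaptic, channel and chromatin genes rose. Postsynaptic genes rose at 4 of 35, 7 over the list alone (adjusted p = 1.63e-07; adjusted p = 0.19 with an estimated correlation), with Shank1 from 216 ± 6.5 to 287 ± 34 CPM and Grin2b at 0.33. Presynaptic genes rose at 5 of 34, 9 up and 1 down over the list alone (adjusted p = 1.7e-05; adjusted p = 0.134 with an estimated correlation), with Bsn from 275 ± 19 to 392 ± 2.4 CPM and Pclo from 262 ± 19 to 359 ± 22 CPM. Ion channels rose at 6 of 35, 13 over the list alone (adjusted p = 6.44e-07; adjusted p = 0.19 with an estimated correlation), with Cacna1c at 0.38 and Scn8a at 0.30. Chromatin regulators rose at 7 of 38, 14 up and 5 down over the list alone (adjusted p = 0.000524; adjusted p = 0.19 with an estimated correlation), with the methyltransferase Kmt2a at 0.46 and the remodeller subunit Arid1a at 0.34. After the length and GC correction the ion channel list (adjusted p = 0.0608) and the chromatin list (adjusted p = 0.619) were no longer called. The postsynaptic median went from 0.128 to 0.0505 and the presynaptic from 0.0712 to 0.0651, and of the single genes in these 4 lists 1 presynaptic gene stayed called.

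The changes followed transcript length. The rank correlation of log2 fold change with transcript length was 0.329, and 167 of the 207 rises lay in the quintile of longest transcripts while 77 of the 133 falls lay in the shortest. Microglial genes, which are few in these cultures, were lower with H2BE as a list of 7, 3 of them over the list alone (adjusted p = 0.000645; adjusted p = 0.19 with an estimated correlation), with Aif1 at 22 counts in Control and 2 in H2BE, a ratio of 0.15 (95% counting interval 0.0171 to 0.61). The microglial call was lost without H2BE replicate 3 (adjusted p = 0.103).

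Smaller lists also moved with H2BE in unstimulated neurons. Secreted factors fell at 1 of 21, Sst (-0.40), and 5 over the list alone (adjusted p = 0.00473; adjusted p = 0.444 with an estimated correlation). Replacement histones fell at H2az2, whose own call was lost as given above, 1 of 11 both over all genes and over the list alone (adjusted p = 0.00154; adjusted p = 0.254 with an estimated correlation). Trk signalling genes rose at 2 of 17, Shc3 (0.44) and Ntrk3 (0.29), and 3 over the list alone (adjusted p = 0.00649; adjusted p = 0.19 with an estimated correlation). ATF4 genes (adjusted p = 0.0105; adjusted p = 0.37 with an estimated correlation) and p53 targets (adjusted p = 0.038; adjusted p = 0.226 with an estimated correlation) were lower, each at 1 gene over the list alone. Without Control replicate 1 the secreted (adjusted p = 0.19) and p53 (0.137) calls were lost, without H2BE replicate 2 the secreted (0.205), ATF4 (0.118) and p53 (0.0514) calls, and without H2BE replicate 3 the p53 call (0.0717). The length and GC correction ended the secreted (0.0616), Trk (0.232), ATF4 (0.131) and p53 (0.0649) calls.

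The 340 genes became 2 without Control replicate 1, 222 without Control replicate 2, 922 without BDNF replicate 1, 908 without BDNF replicate 2, 11 without H2BE replicate 2 and 176 without H2BE replicate 3. After the length and GC correction 35 genes were called, 28 of the 340 among them. Fitted alone, the Control and H2BE libraries gave 1144 calls, all 340 among them. The BDNF libraries enter this comparison only through the gene filter, the scaling and the spread shared by all groups.

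**Figure D3:**
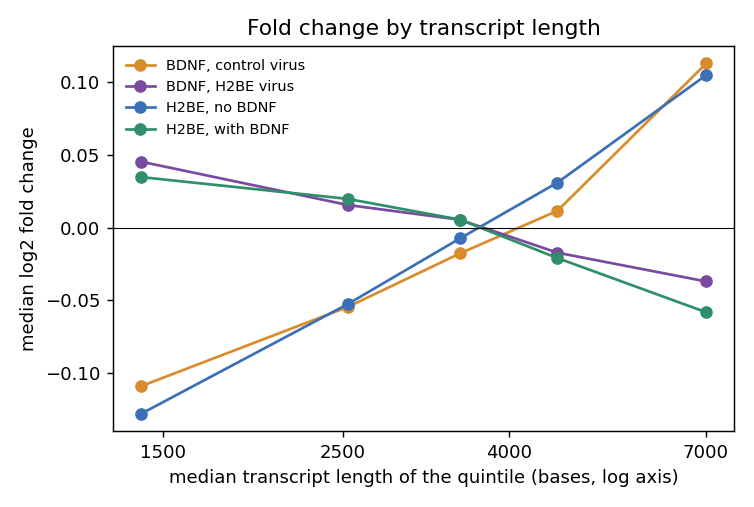
Median log2 fold change of each quintile of transcript length (vertical axis) against the median transcript length of the quintile in bases (horizontal axis, log scale), in the 4 pairwise comparisons. For H2BE against Control the median goes from -0.128 in the shortest quintile to 0.105 in the longest.

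With BDNF present, H2BE changed few genes. Besides H2bc21, Cntn6, a neuronal adhesion molecule, rose from 23.2 ± 1.7 to 35.2 ± 2.4 CPM (log2 fold change 0.65, adjusted p = 0.0239, n = 2). Cort, the neuropeptide cortistatin of interneurons, fell from 35.3 ± 9 to 18.8 ± 1.2 CPM (-0.92, adjusted p = 0.0343), and Slc7a1, an arginine and lysine transporter, from 270 ± 6.3 to 212 ± 5.5 CPM (-0.33, adjusted p = 0.0488). These 4 genes were all that edgeR called, with 1516 at an unadjusted p below 0.05, and DESeq2 called 12, with 1 of these 4 among them. Its filter left H2bc21, Cntn6 and Cort without an adjusted p. The calls of Cntn6, Cort and Slc7a1 were lost when only the BDNF and H2BE+BDNF libraries were fitted.

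Interneuron genes were lower with H2BE under BDNF as a list, though none of the 22 passed over all genes in edgeR. Over the list alone 8 fell and 1 rose (adjusted p = 8e-08; adjusted p = 0.181 with an estimated correlation), with log2 fold changes of -0.36 for Sst, -0.33 for the vesicular GABA transporter Slc32a1, -0.39 for Nxph1 and -0.24 for Gad1. No gene of the next 3 lists passed over all genes either. Genes of the mitochondrial genome were higher, 4 of 8 over the list alone (adjusted p = 2.49e-07; adjusted p = 0.226 with an estimated correlation). ATF4 and unfolded protein genes were lower, 5 of 28 over the list alone (adjusted p = 6.65e-05; adjusted p = 0.226 with an estimated correlation), as were astrocyte genes, 6 of 16 (adjusted p = 0.000716; adjusted p = 0.285 with an estimated correlation), with Mlc1 at -0.98. The ATF4 call was lost without BDNF replicate 1 (adjusted p = 0.058), the astrocyte call without BDNF replicate 2 (adjusted p = 0.0796) and the mitochondrial call with replicates 2 and 3 alone (adjusted p = 0.0624). The 4 genes became 762 without BDNF replicate 1, 10 without BDNF replicate 2, 2 without H2BE+BDNF replicate 2 and 1 without H2BE+BDNF replicate 3.

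The ion channel and presynaptic lists, called higher with H2BE in unstimulated neurons, were called lower with H2BE under BDNF, with no member passing over all genes in edgeR. Ion channels were lower at 4 of 35 over the list alone (adjusted p = 0.000151; adjusted p = 0.226 with an estimated correlation), presynaptic genes at 5 of 34 with 2 higher (adjusted p = 0.0186; adjusted p = 0.19 with an estimated correlation), and GABA genes at 5 of 22 with 1 higher (adjusted p = 0.0208; adjusted p = 0.595 with an estimated correlation). Secreted factors, Cort among them, were lower at 5 of 21 with 1 higher (adjusted p = 0.00847; adjusted p = 0.459 with an estimated correlation), and ribosomal protein genes were called higher with no single gene passing over the list alone (adjusted p = 0.000203; adjusted p = 0.594 with an estimated correlation). Leaving out BDNF replicate 2 ended the GABA (adjusted p = 0.761), secreted (0.228) and ribosomal (0.268) calls, H2BE+BDNF replicate 2 the GABA call (0.095), and H2BE+BDNF replicate 3 the secreted (0.18) and presynaptic (0.133) calls. The length and GC correction ended the channel (0.0546), presynaptic (0.183), GABA (0.0585) and ribosomal (0.131) calls.

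Across 13452 genes the log2 fold changes of H2BE with and without BDNF had a Pearson correlation of 0.0943, against 0.00704 in simulations without effects, and a rank correlation of 0.0126. Of the 340 genes called without BDNF 33.8% had the same sign with BDNF. The mitochondrial list was called up in both, and the ATF4 and secreted lists down in both, with the losses given above. The correlation was 0.0606 without Control replicate 1 and 0.0467 without H2BE+BDNF replicate 2.

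**Figure D4:**
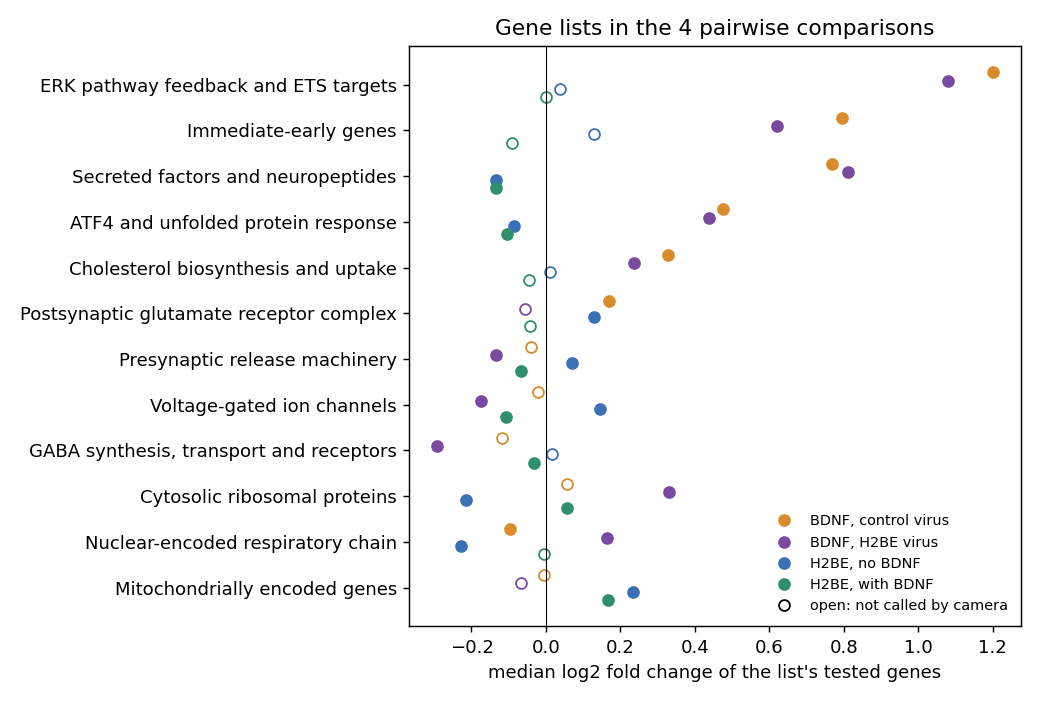
Median log2 fold change (horizontal axis) of 12 gene lists (vertical axis) in the 4 pairwise comparisons, with open symbols where the list test made no call. ERK feedback genes have medians of 1.2 and 1.08 with BDNF under the control and H2BE viruses.

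The BDNF response of some genes differed between the viruses. Trpc5, a cation channel of growth cones, went from 2.9 ± 1.1 to 10.3 ± 2.8 CPM with BDNF under the control virus and from 6.37 to 6.52 CPM under the H2BE virus (log2 difference of responses -1.87, adjusted p = 0.0345, n = 2). Slc7a11, which imports cystine for glutathione, went from 3.48 ± 0.49 to 10.2 ± 1 CPM and from 5.03 to 5.35 CPM (-1.59, adjusted p = 0.0357). Bsn went from 275 to 467 CPM and from 392 to 398 CPM (-0.69). Rps14 went the other way, from 179 to 140 CPM under the control virus and from 132 to 156 CPM under the H2BE virus (0.55). In all, 191 genes were called, 57 with a higher response under the H2BE virus and 134 with a lower one. DESeq2 called 204.

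The largest lower responses after these were Dyrk1b (-1.18), the metalloprotease Adam12 (-1.17) and the ephrin receptor Epha6 (-1.13). The largest higher ones were the lysine methyltransferase Eef1akmt2 (0.89), Frg1 (0.87), the mitochondrial fission adaptor Mief2 (0.85), Wdr83os (0.81) and Dpy30 (0.80), a subunit of histone H3 methyltransferases. The 10 genes named as the 5 largest in each direction lost their call after the length and GC correction, but not always their size. The same held without Control replicate 1, H2BE replicate 2 or H2BE+BDNF replicate 2. Thinning to the smallest library ended the calls of Adam12 (-0.691, adjusted p = 0.287), Slc7a11 (-1.197, 0.167), Eef1akmt2, Epha6, Mief2 and Dpy30. Trpc5, Dyrk1b, Frg1 and Wdr83os kept theirs there. After the correction Trpc5 was at -1.85, Slc7a11 at -1.45, Dyrk1b at -1.18, Epha6 at -1.12 and Mief2 at 0.82. Adam12 went to -0.99, Eef1akmt2 and Frg1 to 0.65, Wdr83os to 0.62 and Dpy30 to 0.52. Without Control replicate 1 Dyrk1b was at -1.20 and Frg1 at 0.95, while Trpc5 went to -1.43, Slc7a11 to -1.32 and Adam12 to -0.805. Ribosomal protein genes had higher responses at 9 of 69, 44 over the list alone (adjusted p = 8.24e-26; adjusted p = 0.226 with an estimated correlation), and respiratory chain genes at 5 of 59, 28 up and 1 down over the list alone (adjusted p = 1.08e-19; adjusted p = 0.19 with an estimated correlation). Ion channels had lower responses at 4 of 35, 15 over the list alone (adjusted p = 1.67e-10; adjusted p = 0.184 with an estimated correlation), as had 2 postsynaptic genes of 35, 10 over the list alone (adjusted p = 1.18e-07; adjusted p = 0.19 with an estimated correlation), and 3 presynaptic genes of 34, 10 over the list alone (adjusted p = 8.49e-07; adjusted p = 0.134 with an estimated correlation). The 191 genes became 2 without Control replicate 1, 917 without BDNF replicate 1, 2 without H2BE replicate 2, 44 without H2BE+BDNF replicate 2 and 26 without H2BE+BDNF replicate 3. After the length and GC correction 4 genes were called, 3 of the 191 among them.

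BDNF and H2BE were each compared with the same Control libraries. Their log2 fold changes had a Pearson correlation of 0.21, and the shared Control libraries alone gave 0.471 in 20 simulations without effects. These correlations cannot be ranked against each other, because the 4228 genes called for BDNF widen the observed changes and the simulations hold no such changes. The covariance was 0.0365 against 0.0254 simulated. With a Control library of its own for each comparison the correlation was 0.0619, and 0.0532 with the libraries exchanged. The correlation was 0.401 without Control replicate 1, 0.34 without Control replicate 2 and 0.0685 without H2BE replicate 2.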

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

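In this part the test of transcript length and GC content as the whole cause of the differing BDNF responses was chosen after that result was seen. The BDNF response differed between the viruses at 191 genes. The count was 2 without Control replicate 1, 2 without H2BE replicate 2 and 4 after the length and GC correction. A group left with 1 library takes its spread from the other groups, so a lost call there is weak evidence against a gene. Without Control replicate 1 Dyrk1b was at -1.20, Frg1 at 0.95, Epha6 at -1.135, Wdr83os at 0.85 and Dpy30 at 0.81. Trpc5 went to -1.43, Slc7a11 to -1.32, Adam12 to -0.805, Eef1akmt2 to 0.81 and Mief2 to 0.76.

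The differing responses follow transcript length, with a rank correlation of -0.356 over all genes and 118 of the 134 lower responses in the quintile of longest transcripts. After correction for length and GC content 1.57% of the 191 genes stayed called, a share within the range set for such a trend as the whole cause. The median difference of the 57 higher genes went from 0.456 (median SE 0.102) to 0.325 (0.0942) with the sign kept at 57, and that of the 134 lower genes from -0.461 (0.0894) to -0.238 (0.0803) with the sign kept at 133. The medians shrank while the errors did not grow, the stricter threshold that follows when few genes pass was not separated from this, and Trpc5 at -1.85 and Dyrk1b at -1.18 kept their size, so the lost calls do not show that the trend accounts for each gene. A weaker BDNF response in neurons with H2BE was tested on genes chosen in 1 pair of Control and BDNF libraries and measured in the other pair. The control-virus response lay above every H2BE pairing at 6 of 9 settings of fold and expression, which leaves that explanation undecided. The prediction had fixed no settings, and the 9 were run after a single setting had met it. No genes were chosen under the H2BE virus, so any difference between the viruses in single genes favours the control-virus response. Among genes called under the control virus the slope of the H2BE-virus response on the control-virus response was 0.775. Taken the other way, among genes called under the H2BE virus, it was 0.804.

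Among genes named for H2BE without BDNF, the difference of BDNF responses was -1.18 for Dyrk1b, -0.85 for Hivep3, -0.93 for Nhsl2, -0.60 for Prr36 and -0.33 for ND4. It was 0.69 for Mrps12, 0.49 for Ndufb7 and 0.52 for Ndufb3, which fell with H2BE in unstimulated neurons. The difference of responses holds the H2BE against Control change of the same libraries with its sign turned, so choosing genes by that change favours the opposite sign. Of the genes named for H2BE under BDNF, Cntn6 had a difference of 0.58 and Slc7a1 of -0.50, where the choice favours the same sign. Besides Dyrk1b, the genes named for the largest lower responses were Trpc5 (-1.87), Slc7a11 (-1.59), Adam12 (-1.17) and Epha6 (-1.13). Those named for the largest higher responses were Eef1akmt2 (0.89), Frg1 (0.87), Mief2 (0.85), Wdr83os (0.81) and Dpy30 (0.80).

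At the preset correlation 11 gene lists differed in their BDNF response, and none did with an estimated correlation. The median difference was 0.286 for ribosomal protein genes and 0.248 for nuclear respiratory genes (0.137 and 0.0815 after the length and GC correction). It was -0.208 for ion channels, -0.203 for postsynaptic and -0.134 for presynaptic genes (-0.11, -0.0738 and -0.0719). These 5 lists stayed called after the correction, with no single member called. Trk receptor genes had a median of -0.184 (adjusted p = 0.00116; adjusted p = 0.19 with an estimated correlation), with lower responses of Shc3 and Ntrk2, and lost their call after the length and GC correction (adjusted p = 0.116). GABA genes had a median of -0.107 (adjusted p = 0.0103; adjusted p = 0.557 with an estimated correlation) and were no longer called without BDNF replicate 2 (adjusted p = 0.434) or H2BE replicate 3 (0.0864). Replacement histones had a median of 0.144 (adjusted p = 0.0182; adjusted p = 0.336 with an estimated correlation), lost without BDNF replicate 2 (adjusted p = 0.155) and after the length and GC correction (0.129). Chromatin regulators had a median of -0.124 (adjusted p = 0.0176; adjusted p = 0.226 with an estimated correlation), with Ep300 at -0.61, lost without BDNF replicate 1 (adjusted p = 0.0525), H2BE replicate 2 (0.0514) or H2BE+BDNF replicate 3 (0.0537), and the median turned to 0.014 after the length and GC correction. Astrocyte genes had a median of -0.346 (adjusted p = 0.0227; adjusted p = 0.428 with an estimated correlation), lost without Control replicate 2 (adjusted p = 0.115), BDNF replicate 2 (0.196) or H2BE replicate 2 (0.167). Microglial genes had a median of 0.544 (adjusted p = 0.0318; adjusted p = 0.291 with an estimated correlation), which ranged from 0.087 to 1.107 when single libraries were left out and was not called in most of those fits.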

How the results depend on the processing

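The replicate number does not pair the samples. After group means were removed, libraries with the same number had correlations of -0.299 to -0.17. A block for that number gave 37 genes for H2BE+BDNF against BDNF, against 4 without it, and a crossed block gave 9.

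The choice that moved most counts was which libraries enter. With all 10 libraries as replicates the calls were 6460 for BDNF against Control, 1644 for H2BE against Control, 28 for H2BE+BDNF against BDNF and 1195 for the difference of responses. Libraries that repeat another's counts lower the apparent spread, which raises the calls by construction. A rounded mean of the overlapping libraries gave 1 gene for H2BE+BDNF against BDNF and 296 for the difference of responses. Replicates 2 and 3 alone gave 1 and 360, and 44 and 380 with the block. Only the groups compared gave 1144 for H2BE against Control and 1 for H2BE+BDNF against BDNF. Libraries outside a comparison enter it only through the gene filter, the scaling and the spread shared by all groups. Among pairs of distinct libraries within a group the spread of counts was largest in BDNF (chi-squared per degree of freedom 5.16), against 1.67 to 1.83 in the other groups. For these counts of calls the cause was not tested.

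DESeq2 gave 2602 genes for BDNF against Control, 2311 for H2BE+BDNF against H2BE and 12 for H2BE+BDNF against BDNF. Without the filter on low counts there were 588 for H2BE against Control, 163 for H2BE+BDNF against BDNF and 434 for the difference of responses. Libraries thinned to the smallest total gave 11 for H2BE+BDNF against BDNF. After the length and GC correction 35 genes were called for H2BE against Control, 28 of the 340 among them. For the difference of responses 4 were called, 3 of the 191 among them. With the block added to the correction the calls were 39 and 17, and 23 for H2BE+BDNF against BDNF. The cause was not tested for the tools and the filter.

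Leaving out single libraries gave 2316 to 4489 genes for BDNF against Control, 2 to 922 for H2BE against Control, 1923 to 4136 for H2BE+BDNF against H2BE, 1 to 762 for H2BE+BDNF against BDNF and 2 to 917 for the difference of responses. The cause was not tested.

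The correlation of the BDNF changes under both viruses was 0.627 to 0.695 when a library was left out, 0.686 with replicates 2 and 3 alone, 0.69 with the block added, and 0.125 without the low-count filter. That of the H2BE changes with and without BDNF was 0.0467 to 0.102 when a library was left out. It was 0.052 without the filter, 0.0337 with replicates 2 and 3 alone and 0.0457 with the block added. It was 0.131 after the length and GC correction and 0.146 with the block added, 0.0554 with 10 libraries, 0.0701 with the crossed block and 0.0589 after thinning. That of BDNF and H2BE changes against the same Control was 0.0685 to 0.401 when a library was left out, 0.379 without the filter, and 0.0619 and 0.0532 with a Control library for each comparison, both ways round. Removing the shared libraries lowers it by construction. The cause was not tested.

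Camera called 58 of 130 list tests at its preset correlation and 0 with an estimated correlation, where 27 had an unadjusted p below 0.05. The smallest adjusted p with an estimated correlation was 0.134, also for ERK feedback genes with BDNF under the control virus (median 1.2). The absence of a call there thus does not separate strong from weak lists. Nuclear respiratory genes with BDNF under the control virus turned to a median of 0.018 after the length and GC correction, with and without the block. Chromatin regulators turned to 0.014 in the difference of responses under the same settings. GABA genes for H2BE+BDNF against BDNF ranged from -0.163 without BDNF replicate 1 to 0.028 without BDNF replicate 2, and turned to 0.003 after the length and GC correction. The cause was not tested.

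H2bc21 kept its call in every setting with an adjusted p. DESeq2 gave it none, because its filter removed the gene, as it did for 29 of 77 named genes and comparisons, among them all 10 named for the difference of responses. It put the log2 fold change for H2BE against Control at 2.93.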

Other observations

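In this part the length test on H2BE+BDNF against BDNF was chosen after the result was seen, and the interval asked of the length bias between libraries was added after its correlations were seen. Cell identity genes moved with BDNF. Of 18 excitatory neuron markers 2 rose and 8 fell with BDNF under the H2BE virus, 2 and 10 over the list alone (adjusted p = 0.00473; adjusted p = 0.19 with an estimated correlation), with the upper-layer factor Cux2 at a log2 fold change of -1.22 and the pallial factor Emx1 at -1.11. Under the control virus 4 rose and 9 fell, with the same counts over the list alone (adjusted p = 0.119), Emx1 from 27.4 to 13.9 CPM and Cux2 from 55.3 to 33.2 CPM. Of 22 interneuron markers 2 rose and 9 fell under the H2BE virus, 3 and 11 over the list alone (adjusted p = 0.00695; adjusted p = 0.254 with an estimated correlation), with Maf at -0.72 and Adarb2 at -0.75. Under the control virus 3 rose and 6 fell, 3 and 7 over the list alone (adjusted p = 0.197), with Calb2 at -0.91 and Sst at -0.37. Of 16 astrocyte markers 3 fell under the H2BE virus (adjusted p = 0.183), among them Glul, which makes glutamine, at -0.62, and under the control virus 2 rose and 1 fell but none over the list alone (adjusted p = 0.965). Of 10 endothelial, mural and fibroblast markers Dcn fell under both viruses (-1.45 and -0.94), and the list was not called in any comparison (adjusted p = 0.44 and 0.382 with BDNF).

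Structural and growth genes split within their lists. Of 30 axon and cytoskeleton genes 9 rose and 16 fell with BDNF under the control virus, 10 and 16 over the list alone (adjusted p = 0.573, the test up and the median -0.179), and the neurofilament genes Nefm (99.5 ± 11 to 294 ± 14 CPM, n = 2) and Nefl (239 to 468 CPM) rose. Under the H2BE virus 9 rose and 17 fell, 9 and 18 over the list alone (adjusted p = 0.573, median -0.189 and mean 0.0177), with Nefl at 1.13 and the microtubule protein gene Dcx at -0.58. Of 17 Trk signalling genes 6 rose and 4 fell under the control virus (adjusted p = 0.207), where the neurotrophin Ntf3 went from 76 counts to 5, the adaptor Shc3 rose by 1.03 and the receptor Ntrk2 fell by 0.30 on the log2 scale. The test pointed up and the median was 0.107, while the mean was -0.121. Of 18 p53 targets 6 rose and 6 fell, with the same counts over the list alone (adjusted p = 0.622, the test up and the median -0.0881), with Cdkn1a from 112 ± 19 to 222 CPM. None of 8 interferon genes changed with BDNF in edgeR (adjusted p = 0.603), although Ifi209 rose. In unstimulated neurons H2BE raised the excitatory list, 1 of 18 and 4 over the list alone (adjusted p = 0.00515; adjusted p = 0.19 with an estimated correlation), with Camk2a from 180 to 225 CPM, and the axon list, 4 up and 1 down, 10 and 3 over the list alone (adjusted p = 0.0133; adjusted p = 0.19 with an estimated correlation), which the length and GC correction ended (adjusted p = 0.0803).

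The link of the H2BE changes to transcript length in unstimulated neurons has several possible explanations. For a difference in library size, the rank correlation was 0.329 before and 0.335 after every library was thinned to the smallest total. That lies in the range set beforehand as arguing against library size. Thinning keeps each gene's expected share of its library, so the value could hardly move, and the test does not decide this explanation. H2BE raising long genes in either treatment predicted a positive rank correlation in H2BE+BDNF against BDNF, where it was -0.175. That value argues against it only if these libraries do not differ in length bias, which is left undecided below. A length-dependent bias between libraries could also produce it, and the mean length slope was -0.0481 ± 0.017 log2 per doubling in Control against 0.0208 ± 0.0012 in H2BE, 0.0323 ± 0.019 in BDNF and -0.00506 ± 0.0042 in H2BE+BDNF, so Control stands apart from BDNF too (rank correlation 0.212 for BDNF against Control). The test of that bias was the correlation across genes of within-group library differences with the H2BE changes. Its 95% intervals count genes as independent and do not measure the spread between libraries. The correlation was -0.0448 (95% interval -0.0617 to -0.0279) within BDNF and 0.0453 (0.0284 to 0.0621) within H2BE+BDNF. Both lie under the 0.05 set beforehand as arguing against the bias, but the upper interval passes it, which leaves it undecided under the interval asked afterwards; within-group differences carried little length signal (rank correlations 0.11 and 0.0452), and a bias that coincides with the Control group would not show there.

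The rise of synaptic and channel genes with H2BE has a related question. If H2BE raised synaptic genes apart from their length, lists called up after length and GC correction were predicted, and 2 of 3 lists were, postsynaptic (median 0.0505, adjusted p = 0.00673) and presynaptic (0.0651, adjusted p = 0.00586). Before the correction neither passed with an estimated correlation (adjusted p = 0.19 and 0.134), and after it 1 presynaptic gene was called singly. The transcript length of the list members may account for part. The 886 unlisted genes matched on length and expression had a median log2 fold change of 0.0478, against 0.126 for the 104 members. The members lay at percentile 100 of 10000 lists drawn at random from the matched genes. Such draws ignore correlation among list members, so the percentile does not measure the spread between libraries. The median of the matched genes lies between the values predicted with and without an effect of length, so the explanation stays open.

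For the BDNF genes under the control virus, chance was tested by regrouping the 4 distinct libraries. There are too few splits, 3, for a share under 0.05: only the real split, 1 of them, reached 4228 calls, and the highest other had 0 in edgeR, with 203 genes at an unadjusted p below 0.05.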
